A study of Homo sapiens with 3 samples.

How the data were processed

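RNA was measured by sequencing in mammospheres of MCF10DCIS breast cells, with 1 library for control, 1 for 1,25D3 and 1 for BXL0124. Per the labels, spheres were grown and treated for 5 days and dissociated with Accutase. RNA was extracted with an AllPrep DNA/RNA kit, and libraries were made from 400 ng of RNA with an Illumina RNA library preparation kit. The submitters' processing notes name alignment with HISAT2 to hg19 and analysis with Cufflinks and Cuffdiff. The deposited tables hold whole-number counts per gene symbol, made by the authors, although their names describe them as FPKM, and per the file headers the counts come from alignments with duplicates removed. The counting tool, the annotation, the strand setting and the versions are not given in the sources used here. The plan made before the data were examined assumed FPKM. CPM, the counts divided by the library total and scaled to a sum of 1000000, took its place, with every other planned setting kept.

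Of 26364 genes, 13188 with at least 1 CPM in at least 1 of the 3 libraries were kept. Ratios were log2 of CPM + 1, and a gene was called at a 2-fold ratio on that scale. No test was run and no p-value computed, because each group had 1 library. Folds printed with an interval are ratios of plain CPM, with exact conditional (Clopper-Pearson) 95% intervals. Low counts were mostly even: among genes with 1 to 20 counts, 69.5% had an even count in control, 64.3% with 1,25D3 and 64.6% with BXL0124. Intervals were therefore computed on read pairs, taking 2 counts as 1 pair, a choice made after the counts were seen. A fold against a library with no count is a bound at a floor of 3 read pairs, equal to 0.157 CPM in control, 0.117 CPM with 1,25D3 and 0.115 CPM with BXL0124. Intervals and floors cover counting error only.

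The 35 gene lists were fixed before the data were examined. They hold 1067 gene symbols, of which 877 were kept, and some genes are in more than 1 list, such as NGFR among both stem cell and basal markers. The median log2 ratio of each list with at least 5 kept members was placed among 10000 random lists matched on mean expression in 20 bins. A list lay apart under percentile 2.5 or over the mirrored upper limit. Intervals of medians are order-statistic 95% intervals across genes. Named genes followed a rule fixed beforehand: the 12 largest and 12 smallest log2 ratios for each compound, and 6 and 6 between compounds, among genes at 5 CPM or more in the higher library. Up to 4 members of each list described were added, with CYP24A1, VDR, RXRA, CD44, CD24, ALDH1A3 and MKI67 in any case. Small RNA genes, histone genes, uncharacterised loci and sex-linked transcripts were left out of the rule, and not every gene it picked is printed; 1 of them is not reported here. The shared control was allowed for in part, with 100 simulations of unchanged libraries. Their noise was taken from the difference between the treated libraries, so a deviation particular to the control library is not covered.

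Alternatives planned beforehand were other pseudocounts and filters, TPM, median ratio centring, upper quartile scaling, other fold thresholds and random lists not matched. TMM scaling (edgeR 4.0.16), DESeq2 1.42.0 size factors and removal of the length and GC trend were added after the data were seen. The trend was removed by lowess with a fraction of 0.3, on transcript length and then on GC content from GENCODE 29, for the 12950 kept genes that could be matched by symbol (98.2%). The 2-fold calls and the list percentiles were tested on simulated data with counting error only. The simulation held no variation between libraries and no length trend, so it gives no rate of false calls for these libraries. Changed genes were planted at 5 CPM or more. For each comparison, all 50 genes planted at each of 4 changes between −3 and 3 on the log2 scale were recovered, and none of 12988 unchanged genes was called. Of 40 unchanged lists, 1, 1 and 2 lay apart in the 3 comparisons. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, matplotlib 3.10.9 and R 4.3.3 were used.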

Results

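RNA-seq counts per gene were analysed for mammospheres of MCF10DCIS, an established human breast cell line that forms lesions resembling ductal carcinoma in situ when grafted into mice. Mammospheres are free-floating clusters, a culture form used to enrich for cells with stem-like properties. The spheres were treated for 5 days, and there were 3 libraries, 1 per group: control, 1,25D3 and BXL0124. The treatment protocol names DMSO beside both compounds. 1,25D3 is the hormonally active form of vitamin D, which acts through the vitamin D receptor, and the labels describe BXL0124 as a vitamin D analog. The labels give no dose. The name of the deposited 1,25D3 table carries 100 nM, and none is given for BXL0124 in the sources used here. The doses of the compounds may therefore differ. Total counts were 38122315 in the control library, 51421412 in the 1,25D3 library and 52261152 in the BXL0124 library, with a count above 0 for 17398, 17377 and 17643 genes. The gene with most counts took 0.546% of the control library and 0.502% of the 1,25D3 library, and was EEF1A1, a translation elongation factor, in both. In the BXL0124 library it was KRT5, a keratin of basal epithelial cells, at 0.491%. There were no replicates, so no difference below has a replicate check, no p-value is given, and every ratio compares libraries, not conditions. Intervals in parentheses after folds are 95% counting intervals, which cover counting error only.

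The first comparison asked how 1,25D3 altered gene expression in the mammospheres, in a study whose title concerns cancer stemness. CYP24A1, the enzyme that inactivates vitamin D hormone and a classic target of the vitamin D receptor, stood at 1.02 CPM (counts scaled to the library total) in control and 1326 CPM with 1,25D3. It was 1296-fold higher (834 to 2137). TRPV6, an epithelial calcium channel and also a receptor target, was 183-fold higher (126 to 277), at 264 CPM against 1.44 CPM. At the other end, FCGBP, a mucin-like secreted protein, was 795-fold lower (419 to 1740), at 0.35 CPM against 278 CPM. CREB3L1, a membrane-bound transcription factor of secretory cells, was 901-fold lower (351 to 3308).

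Other genes at the higher end were CASP14, a caspase of keratinocyte differentiation, at 245 CPM against 8.05 CPM, and SULF1, a heparan sulfatase, at 34.1 CPM against 1.02 CPM. IRS1, an adaptor of the insulin and IGF receptors, was 22.5-fold higher (15.9 to 33.0), and TREM1, a receptor best known from myeloid cells, was 13.9-fold higher (12.4 to 15.7). COL17A1, a hemidesmosomal collagen, was 10.4-fold higher (9.86 to 10.9), and AHNAK2 was 10.3-fold higher (9.84 to 10.8). IGSF9B and TMEM91 were 29-fold (16.4 to 56.5) and 16.6-fold (11.4 to 24.9) higher. CYP4F3, a fatty acid hydroxylase, was at 35.5 CPM against 1.47 CPM, a value that is uncertain because closely related CYP4F genes can share its reads.

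At the lower end, GDF15, a stress-induced secreted cytokine, was 35.4-fold lower (31.5 to 40), at 11.2 CPM against 396 CPM. MUC5AC, a gel-forming mucin, was 195-fold lower (100.4 to 439). BPIFB1, a secreted airway defence protein, was 98.6-fold lower (65.5 to 156). CALML5, a calmodulin-like protein of epidermis, was 43.9-fold lower (33.0 to 59.8). ENPP3 and FAM3D were 46.3-fold (33.9 to 64.8) and 35.7-fold (27.2 to 47.8) lower. CLDN10, a claudin of tight junctions, was 154-fold lower (62.9 to 516), and CAMK2B, a calcium-dependent kinase, was 26.1-fold lower (22.6 to 30.4). CYP4Z1 was at 0.797 CPM against 55.8 CPM and OBP2B at 0.0972 CPM against 28.5 CPM. Both of these have near-identical copies that can share reads, so their values are uncertain.

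Of 13188 genes at 1 CPM or more in at least 1 library, 940 were at least 2-fold higher and 1006 at least 2-fold lower in the 1,25D3 library on the scale log2(CPM + 1). At least 4-fold differences numbered 136 higher and 177 lower. For all of these 2-fold genes the counting interval excluded 1. With the pseudocount used and at this depth any 2-fold call does so, which adds no support. The share of higher genes among the 2-fold genes was 48.3%, and 62.8% after rescaling to TPM, which moved the median log2 ratio of all genes from −0.05 to 0.12. Ratios followed transcript length: across 12950 genes, which are not independent replicates, Spearman's rho between log2 ratio and transcript length was 0.467. The median log2 ratio was −0.50 for the 2268 genes with transcripts under 1500 nt and 0.56 for the 1502 genes over 6000 nt. After removal of the length and GC trend, 616 of the 12950 genes were at least 2-fold higher and 862 at least 2-fold lower.

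Of 34 gene lists with at least 5 measured members, 8 lay higher and 8 lower than the central 95% of expression-matched random lists. Lists of independent genes would give 1.7. Genes within a list are not independent and some lists share members, so that number does not measure chance here. The list of vitamin D receptor targets and vitamin D metabolism had 20 of 38 measured members at least 2-fold higher and 2 at least 2-fold lower. Its median log2 ratio was 1.09 (95% interval across genes 0.23 to 1.60), at percentile 100 of the random lists. CAMP, an antimicrobial peptide counted among receptor targets, went the other way, at 34.4 CPM against 127 CPM. VDR, the receptor itself, was at 41.1 CPM against 41.6 CPM in control, and RXRA, its dimerization partner, at 201 CPM against 175 CPM.

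Markers of basal and myoepithelial cells were higher and markers of luminal cells lower with 1,25D3. Among 25 basal markers, 12 were at least 2-fold higher and 2 at least 2-fold lower, with a median log2 ratio of 0.99 (0.44 to 1.53) at percentile 100. EGFR, the epidermal growth factor receptor, was at 183 CPM against 17.9 CPM, while NGFR, a neurotrophin receptor, was lower, at 17.7 CPM against 379 CPM. Among 23 luminal markers, 13 were at least 2-fold lower and 1 at least 2-fold higher, with a median of −1.11 (−1.90 to −0.72) at percentile 0. SPDEF, a transcription factor of secretory luminal cells, was at 11.1 CPM against 257 CPM. TFF3, a secreted trefoil peptide, was at 0 counts with 1,25D3 and 10.5 CPM in control, at least 89.7-fold lower against a floor of 3 read pairs, with a counting interval that starts at 72.3-fold. KRT5, FOXA1 and GATA3, a basal keratin and a pair of luminal transcription factors, were chosen after their values were seen. KRT5 was at 3971 CPM against 482 CPM, FOXA1 at 31.4 CPM against 158 CPM and GATA3 at 53.7 CPM against 128 CPM. ESR1, the estrogen receptor, was the 1 luminal marker at least 2-fold higher, at 4.43 CPM against 0.525 CPM. Of the 23 luminal markers 3 had a ratio above 0, among them MUC1, a membrane mucin, at 205 CPM against 152 CPM.

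Further lists higher with 1,25D3 covered adhesion and matrix. Epithelial junction genes had a median log2 ratio of 0.58 (0.01 to 1.02) at percentile 100, with 10 of 30 at least 2-fold higher and 2 lower. DSP, a desmosomal plaque protein, was at 1070 CPM against 280 CPM, whereas CLDN3, a claudin, was at 1.05 CPM against 9.23 CPM. Genes of the extracellular matrix and integrins had a median of 0.84 (0.37 to 1.15) at percentile 100, with 14 of 37 at least 2-fold higher and 1 lower, and a median transcript length of 5725 nt. After removal of the length and GC trend their median was 0.31 (−0.03 to 0.83), at percentile 99.95. LAMA3, a laminin chain of epithelial basement membranes, was at 421 CPM against 69.2 CPM. Genes of G2 and mitosis had a median of 0.42 (0.12 to 0.61) at percentile 99.95, with 3 of 35 at least 2-fold higher and none lower, and one of 0.21 (0.08 to 0.41) after removal of the trend. ASPM, a spindle pole protein, was at 87.2 CPM against 32.1 CPM, and MKI67, a proliferation marker, at 338 CPM against 158 CPM. No CPM value of a single gene printed here is corrected for the length trend. BIRC5 and UBE2C, which act in mitosis, were lower, at 103 CPM against 128 CPM and 31.5 CPM against 43.6 CPM. DNA replication genes lay inside the central 95%, with a median of 0.09 (−0.03 to 0.23) at percentile 81.5. After removal of the trend they lay above it, with a median of 0.12 (−0.08 to 0.20) at percentile 97.7. PCNA, a replication clamp, was lower, at 72.0 CPM against 132 CPM. The hypoxia list had a median of 0.41 (0.12 to 0.63) at percentile 99.8, which was 0.27 (0.12 to 0.52) after removal of the trend, with LOX, a collagen-crosslinking enzyme, at 427 CPM against 80.7 CPM. Genes of calcium and phosphate handling had a median of 0.41 (−0.29 to 0.98) at percentile 99.1, but lay at percentile 71.5 with no filter on low values. The list of NF-kB and inflammatory cytokines had a median of 0.29 (−0.06 to 0.62) at percentile 98.5, and lay inside the central 95% with a minimum of 5 CPM, at percentile 95.8.

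Lists lower with 1,25D3 included innate defence, mitochondrial and ribosomal genes. Of 25 innate defence genes and secreted protease inhibitors, 13 were at least 2-fold lower and 2 at least 2-fold higher, with a median log2 ratio of −1.09 (−1.34 to 0.17) at percentile 0, and one of −0.71 (−1.09 to −0.08) after removal of the length and GC trend. LCN2, an iron-binding defence protein, was at 21.9 CPM against 431 CPM, and CD14, a lipopolysaccharide co-receptor and vitamin D target, was higher, at 155 CPM against 19.5 CPM. All but 1 of 45 nuclear genes of oxidative phosphorylation had a ratio below 0, with a median of −0.68 (−0.83 to −0.57) at percentile 0, and 4 of them were at least 2-fold lower. All 54 cytosolic ribosomal protein genes had a ratio below 0, with a median of −0.44 (−0.50 to −0.41) at percentile 0, and none reached 2-fold. These lists hold short transcripts, with median lengths of 1098 nt and 811 nt, and after removal of the trend the ribosomal median was 0.023, at percentile 32.6. The oxidative phosphorylation median was then −0.31 (−0.40 to −0.21), at percentile 0. The NRF2 and antioxidant list had a median of −0.49 (−0.70 to −0.05) at percentile 0.05, which was −0.22 at percentile 1.44 after removal of the trend, with NQO1, a quinone reductase, at 162 CPM against 798 CPM. The list of interferon response genes had a median of −0.55 (−0.86 to 0.02) at percentile 0.2, with 9 of 34 at least 2-fold lower and 3 higher, but lay at percentile 3.64 with a minimum of 5 CPM. Its median was −0.36 (−0.65 to −0.22) after removal of the trend. Antigen presentation genes had a median of −0.53 (−0.83 to −0.15) at percentile 0.38, which was −0.12 at percentile 29 after removal of the trend. The unfolded protein response list had a median of −0.33 (−0.50 to −0.15) at percentile 1.95, and lay at percentile 5.16 among random lists not matched on expression. After removal of the trend its median was −0.41 (−0.56 to −0.25), at percentile 0.01. After rescaling to TPM, which moved the median of all genes by a similar amount, the median was −0.13 for the unfolded protein response, −0.29 for NRF2, −0.33 for antigen presentation and −0.24 for ribosomal genes. XBP1, a transcription factor of that response and a luminal gene, was at 96.3 CPM against 639 CPM.

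Stem cell and mesenchymal genes lay inside the central 95% with 1,25D3, with wide intervals, and crossed it under other settings. The 18 measured breast cancer stem cell markers lay at percentile 52.6, with a median log2 ratio of −0.09 (−0.67 to 0.81), which was above 0 after rescaling to TPM. After removal of the length and GC trend their median was −0.35, at percentile 2.0, below the central 95%. CD44, a hyaluronan receptor used to sort stem-like breast cells, was at 669 CPM against 708 CPM. CD24, used with it as a negative marker, was at 654 CPM against 604 CPM. ALDH1A3, an aldehyde dehydrogenase, was at 586 CPM against 639 CPM. At least 2-fold differences numbered 3 higher and 2 lower among the 18. PROCR, the protein C receptor, was higher, at 24.2 CPM against 7.63 CPM, and BMI1 at 4.59 CPM against 1.18 CPM. PROM1, the stem cell marker CD133, was lower, at 1.58 CPM against 8.32 CPM. Mesenchymal and invasion genes lay at percentile 94.1 with a median of 0.16 (−0.54 to 1.07), and above the central 95% under median ratio centring and under TMM scaling, at percentile 98.5 in both. SNAI2, a transcription factor, was at 32.3 CPM against 4.77 CPM, and S100A4 at 12.6 CPM against 93.6 CPM. Of the pluripotency factors only 4 were measured, too few for a percentile, with MYC at 392 CPM against 216 CPM.

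**Figure D1:**
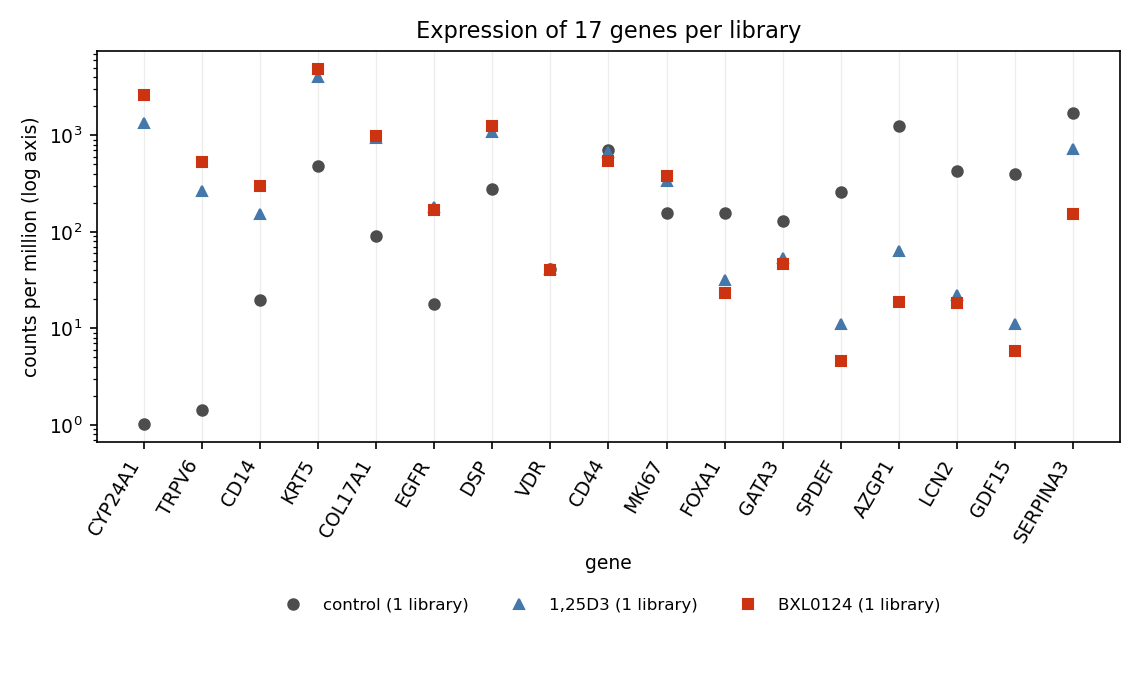
CPM on a log axis for 17 genes, with 1 symbol per library (circle control, triangle 1,25D3, square BXL0124) and no error bars because each group has 1 library. CYP24A1, TRPV6, KRT5 and COL17A1 lie higher in both treated libraries, FOXA1, GATA3, SPDEF, AZGP1, LCN2 and GDF15 lie lower, and VDR lies between 40.3 and 41.6 CPM in all 3.

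The second comparison asked the same of BXL0124. CYP24A1 was 2557-fold higher than in control (1646 to 4216), at 2616 CPM, and TRPV6 was 370-fold higher (255 to 560), at 534 CPM. CD274, the immune checkpoint ligand PD-L1, was 39.3-fold higher (24.1 to 69.1), at 33.0 CPM against 0.839 CPM, and CD14 was 15.3-fold higher (13.8 to 17), at 299 CPM. AZGP1, a secreted zinc-binding glycoprotein of luminal secretory cells, was 67.0-fold lower (61.2 to 73.4), at 18.6 CPM against 1247 CPM. NGFR was 67.3-fold lower (57.2 to 79.8), at 5.63 CPM. KRT5 was at 4910 CPM, FOXA1 at 23.4 CPM and GATA3 at 46.6 CPM.

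Other genes at the higher end were shared with 1,25D3: CASP14 was 40.6-fold higher (34.6 to 48.0), SULF1 was 52.3-fold higher (33.5 to 86.4) and IRS1 was 32.5-fold higher (23.0 to 47.6). TMEM91 and IGSF9B were 32.9-fold (22.8 to 49.4) and 44.1-fold (25.1 to 85.7) higher, and CYP4F3 was at 73.5 CPM. PRRT2 was at 18.5 CPM against 0.184 CPM in control. IGFL3, an IGF-like secreted protein, had no count in control and 17.5 CPM with BXL0124, at least 111-fold higher against the floor, with a counting interval that starts at 90.1-fold. At the lower end, FCGBP was 606-fold lower (347 to 1174) and CREB3L1 was 732-fold lower (313 to 2257). CAMK2B was 270-fold lower (171 to 452), BPIFB1 was 288-fold lower (146 to 668) and MUC5AC was 280-fold lower (128 to 765). STAC2 and FAM3D were 349-fold (149 to 1076) and 131-fold (79.0 to 234) lower, and GDF15 was 68.1-fold lower (58.0 to 80.4), at 5.82 CPM. ENPP3 was at 0.0383 CPM, which is 2 counts, against 73.8 CPM. CYP4Z1 had no count with BXL0124 and was at least 486-fold lower against the floor, with a counting interval that starts at 395-fold and the same uncertainty from its copies.

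The genes at least 2-fold higher numbered 1158 and those at least 2-fold lower 1400, of 13188. At least 4-fold differences numbered 212 and 324. For all of these 2-fold genes the counting interval excluded 1, as it does for any 2-fold call here. The share of higher genes among the 2-fold genes was 45.3%, and 62.3% after rescaling to TPM, where the median of all genes was 0.15 and not −0.06. Spearman's rho with transcript length was 0.426 across the same 12950 genes, with a median log2 ratio of −0.53 for the short and 0.57 for the long transcripts. After removal of the length and GC trend, 809 of these genes were at least 2-fold higher and 1187 at least 2-fold lower.

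With BXL0124, 6 lists lay higher and 9 lower than the central 95%. Vitamin D receptor targets had 23 of 38 members at least 2-fold higher and 3 lower, with a median log2 ratio of 1.47 (0.34 to 2.30) at percentile 100. VDR was at 40.3 CPM and RXRA at 202 CPM. Basal markers had a median of 1.03 (0.09 to 1.60) at percentile 100, with 14 of 25 at least 2-fold higher and 3 lower, among them COL17A1 at 973 CPM and EGFR at 170 CPM. Luminal markers had a median of −1.44 (−2.05 to −0.82) at percentile 0, with 13 of 23 at least 2-fold lower and 1 higher. SPDEF was at 4.61 CPM, TFF3 had no count and was at least 91.2-fold lower against the floor, with a counting interval that starts at 73.5-fold, and ESR1 was at 5.26 CPM. Epithelial junction genes had a median of 0.72 (0.00 to 0.88) at percentile 100, with DSP at 1234 CPM, and one of 0.34 (0.06 to 0.70) after removal of the length and GC trend. CTNND1, the catenin p120, was at 9.01 CPM against 1.15 CPM, a value that is uncertain because it overlaps a read-through gene. Matrix and integrin genes had a median of 0.82 (0.17 to 1.10) at percentile 100, with LAMA3 at 416 CPM, and one of 0.23 (−0.28 to 0.93) after removal of the trend. Genes of G2 and mitosis had a median of 0.31 (0.05 to 0.57) at percentile 98.6, which was 0.17 (0.02 to 0.39) after removal of the trend, with ASPM at 94.6 CPM and MKI67 at 382 CPM. The DNA replication list lay inside the central 95% (0.07, percentile 79.1). The fatty acid and triglyceride synthesis list had a median of 0.46 (−0.63 to 1.07) at percentile 99.6, with 7 of 24 at least 2-fold higher and 4 lower, and lay at percentile 97.1 with a median of 0.22 after removal of the trend. FADS1, a fatty acid desaturase, was at 479 CPM against 44.5 CPM, while DGAT2, an enzyme of triglyceride synthesis, was at 2.95 CPM against 30.3 CPM.

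Innate defence genes had a median log2 ratio of −1.02 (−1.61 to −0.20) with BXL0124, at percentile 0, with 13 of 25 at least 2-fold lower and 2 higher, and one of −0.64 (−1.18 to −0.20) after removal of the length and GC trend. LCN2 was at 18.2 CPM. Oxidative phosphorylation genes had a median of −0.65 (−0.86 to −0.55) and ribosomal protein genes one of −0.59 (−0.65 to −0.54), both at percentile 0, and after removal of the trend these were −0.30 (−0.42 to −0.19) at percentile 0.11 and −0.12 (−0.19 to −0.05) at percentile 5.10. Interferon response genes had a median of −0.64 (−1.21 to 0.16) at percentile 0.06, with 16 of 34 at least 2-fold lower and 3 higher, and lay at percentile 6.24 with a minimum of 5 CPM. IFITM1, an interferon-induced membrane protein, was at 0.861 CPM against 20.3 CPM. Antigen presentation genes had a median of −0.78 (−1.04 to −0.32) at percentile 0.04, which was −0.48 (−0.60 to −0.11) after removal of the trend, with PSMB8, an immunoproteasome subunit, at 14.9 CPM against 58.1 CPM. The Wnt list had a median of −0.85 (−1.05 to −0.25) at percentile 0.01, with 8 of 21 at least 2-fold lower and none higher. With a minimum of 5 CPM its median was −0.33 at percentile 12.2, and after rescaling to TPM −0.48. With 1,25D3 the Wnt list had a median of −0.27 (−1.13 to −0.08) at percentile 14.3, and one of −0.62 (−1.03 to −0.36) at percentile 0 after removal of the trend, so a difference between the compounds is not shown. WNT4, a Wnt ligand, was at 0.249 CPM against 3.41 CPM. The unfolded protein response list lay inside the central 95%, with a median of −0.30 (−0.77 to −0.19) at percentile 4.91. After removal of the trend it lay below, with a median of −0.39 (−0.60 to −0.24) at percentile 0.24, as with 1,25D3. Cell cycle inhibitors and p53 targets had a median of −0.34 (−0.70 to −0.10) at percentile 2.34, with BBC3, a pro-apoptotic protein, at 4.0 CPM against 23.7 CPM. Housekeeping genes had a median of −0.34 (−0.61 to 0.02) at percentile 2.48. These last lists lay inside the central 95% under several other settings, such as a minimum of 5 CPM, and their medians were −0.21 and −0.18 after removal of the trend. The hypoxia list lay inside the central 95%, with a median of −0.05 (−0.45 to 0.25) at percentile 43.1, which was above 0 under TMM scaling and after rescaling to TPM. Mesenchymal and invasion genes lay inside it, with a median of −0.39 (−0.97 to 0.37) at percentile 7.77, and below it with a pseudocount of 0.1 (−0.72, percentile 0.265) and after removal of the trend (−0.50, percentile 0.32). Stem cell markers lay inside it, at percentile 32.5 with a median of −0.21 (−0.77 to 0.47), which was above 0 after rescaling to TPM. CD44 was at 547 CPM, CD24 at 520 CPM and ALDH1A3 at 553 CPM. PROM1 was lower, as with 1,25D3, at 0.134 CPM against 8.32 CPM in control. PROCR, at 21.9 CPM, and BMI1, at 2.93 CPM, were higher than in control, also as with 1,25D3. Of the 18 stem cell markers, 1 was at least 2-fold higher and 3 lower.

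**Figure D2:**
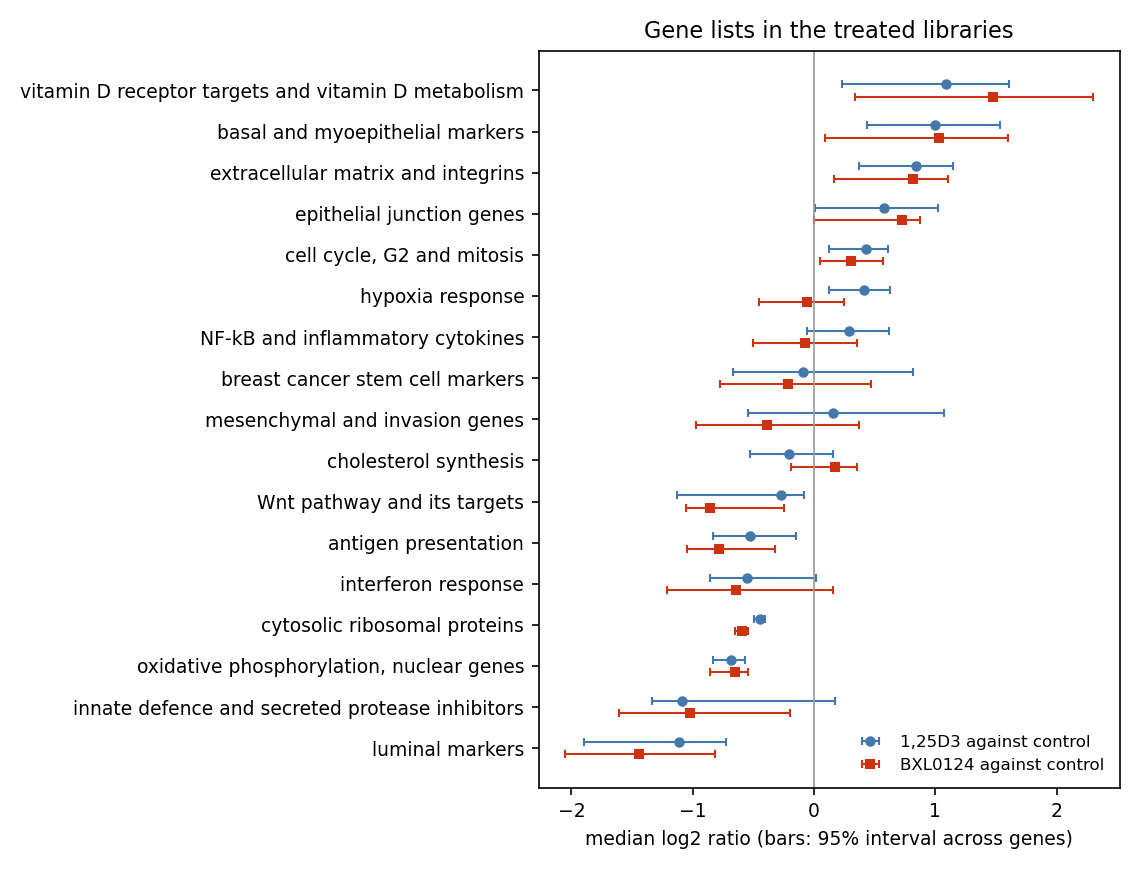
Median log2 ratio of the genes of 17 lists in the 1,25D3 library (circles) and the BXL0124 library (squares) against control, with bars for the 95% interval of the median across genes, which covers no replicate error. Vitamin D receptor targets (1.09 and 1.47) and basal markers (0.99 and 1.03) lie to the right of 0, and luminal markers (−1.11 and −1.44) to the left.

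The third comparison set the analog against 1,25D3 after the same 5 days, at doses that may differ, so potency was not compared. The treated libraries were close to each other: across kept genes, which are not independent replicates, Pearson's correlation of log2(CPM + 1) was 0.99 between them, 0.93 between control and 1,25D3 and 0.91 between control and BXL0124. Several vitamin D target genes were higher with BXL0124. CYP24A1 was 1.97-fold higher (1.95 to 2.0) and TRPV6 was 2.02-fold higher (1.97 to 2.08). CD274 was 2.16-fold higher (1.92 to 2.44) and CD14 was 1.93-fold higher (1.86 to 2.01). The largest differences were on the lower side. IGFBP5, a binding protein of insulin-like growth factors, was 42.7-fold lower with BXL0124 (18.7 to 124), at 0.210 CPM against 8.98 CPM.

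SLC5A1, an intestinal-type sodium-glucose transporter, was 9.35-fold lower with BXL0124 than with 1,25D3 (7.25 to 12.2), at 2.54 CPM against 23.8 CPM. CX3CL1, a membrane-bound chemokine, was 6.49-fold lower (5.05 to 8.46). CAMK2B was 10.3-fold lower (6.40 to 17.7) and STAC2 was 28.8-fold lower (12 to 89.9). SERPINA3, an acute-phase protease inhibitor, was 4.72-fold lower (4.56 to 4.89), at 152 CPM against 719 CPM and 1690 CPM in control. On the higher side, PRRT2 was 4.63-fold higher (3.73 to 5.78), IGFL3 was 3.80-fold higher (3.10 to 4.69) and NKPD1 was 2.93-fold higher (2.53 to 3.40). ZBED6CL was 3.34-fold higher (3.05 to 3.66), at 79.2 CPM against 23.7 CPM. KRT16P3 was at 26.7 CPM against 7.6 CPM and LGALS9C at 62.7 CPM against 21.3 CPM, and both are uncertain because KRT16P3 is a pseudogene of a keratin and LGALS9C has near-identical copies. Between the treated libraries, 37 genes were at least 2-fold higher with BXL0124 and 140 at least 2-fold lower, of 13188. For each the counting interval excluded 1, as it does for any 2-fold call here. The share of higher genes was 20.9%, and 53.4% after rescaling to TPM. No interval of the difference between compounds across replicates can be given, and a gene not among these is not shown to respond alike.

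Between the compounds, 4 lists lay higher with BXL0124 and 11 lower. Vitamin D receptor targets had a median log2 ratio of 0.32 (0.11 to 0.55) at percentile 100, with 28 of 38 above 0, 3 at least 2-fold higher and 2 at least 2-fold lower. STC1, a secreted regulator of calcium and phosphate, went the other way, 2.04-fold lower with BXL0124 (1.91 to 2.17). Cholesterol synthesis genes had a median of 0.21 (0.14 to 0.33) at percentile 100, with 23 of 25 above 0, and MVK, mevalonate kinase, was at 232 CPM against 140 CPM. Fatty acid and triglyceride synthesis genes had a median of 0.14 (0.07 to 0.36), with FADS1 2.33-fold higher (2.26 to 2.41). The NRF2 and antioxidant list had a median of 0.18 (0.09 to 0.34) at percentile 100, with ME1, malic enzyme, at 174 CPM against 124 CPM. All 30 measured hypoxia response genes had a ratio below 0, with a median of −0.44 (−0.64 to −0.21) at percentile 0. EGLN3, an oxygen-sensing hydroxylase induced by hypoxia, was at 9.59 CPM against 24.8 CPM, and BHLHE41, a hypoxia-induced repressor, at 11.9 CPM against 26.5 CPM. Inflammatory genes of the NF-kB list had a median of −0.29 (−0.51 to −0.01) at percentile 0, with IL1A, interleukin 1 alpha, at 15.5 CPM against 27.3 CPM. Mesenchymal and invasion genes had a median of −0.34 (−0.69 to −0.09), with 22 of 27 below 0 and SPARC, a matrix glycoprotein, at 90.9 CPM against 170 CPM. Stem cell markers had a median of −0.21 (−0.47 to −0.02) at percentile 0.11, with 14 of 18 below 0, and lay at percentile 3.76 with no filter on low values.

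Antigen presentation genes had a median log2 ratio of −0.25 (−0.41 to −0.06) between the compounds, and cell cycle inhibitors and p53 targets one of −0.23 (−0.36 to −0.16), with 26 of 30 below 0. Innate defence genes had a median of −0.19 (−0.37 to 0.00) at percentile 0.065, and lay at percentile 9.84 with no filter on low values. Ribosomal protein genes had a median of −0.16 (−0.17 to −0.15), with 53 of 54 below 0. After removal of the length and GC trend it was −0.14 (−0.17 to −0.12), at percentile 0.01. Notch pathway genes had a median of −0.13 (−0.19 to −0.05) at percentile 0.67, with LFNG, a modifier of Notch receptors, at 1.78 CPM against 4.67 CPM. Genes of the TGF-beta and BMP pathway had a median of −0.11 (−0.33 to 0.10), with BAMBI, a pseudoreceptor, at 13.1 CPM against 30.7 CPM. The list of receptor tyrosine kinases and their ligands had a median of −0.10 (−0.38 to 0.02), with FGFR1, a fibroblast growth factor receptor, at 6.68 CPM against 14.6 CPM. Basal markers (−0.04), luminal markers (−0.08) and oxidative phosphorylation genes (0.01) lay inside the central 95%, which does not show that the compounds act alike on them.

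Most genes at least 2-fold apart from control with 1,25D3 were so with BXL0124 in the same direction. The genes higher with both numbered 815, 86.7% of those higher with 1,25D3 and 70.4% of those higher with BXL0124. The genes lower with both numbered 912, 90.7% and 65.1%. Independent lists would share 82.5 and 107 genes. Simulated unchanged libraries against the shared control gave a median of 2 genes in each direction. Across genes, which are not independent replicates, the log2 ratios of the compounds had a Pearson correlation of 0.951 (0.501 simulated), a Spearman correlation of 0.943 (0.478 simulated) and the same sign for 91.0% of genes (66.7% simulated). Their covariance was 0.693, against 0.0439 simulated. The simulated noise came from the difference between the treated libraries, so a deviation of the control library is not in it. The control could not be split because it is 1 library, so how much of the excess comes from the shared control cannot be told. Among the 940 genes at least 2-fold higher with 1,25D3, the BXL0124 log2 ratio was a median 1.07 times the 1,25D3 log2 ratio (1.05 to 1.08 across genes), and it was the larger for 634 genes. Among the 1006 lower genes the median was 1.10 times (1.09 to 1.12), and the BXL0124 ratio went further for 714 genes. IGFBP5 was the 1 gene at least 2-fold higher with 1,25D3 and at least 2-fold lower with BXL0124.

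**Figure D3:**
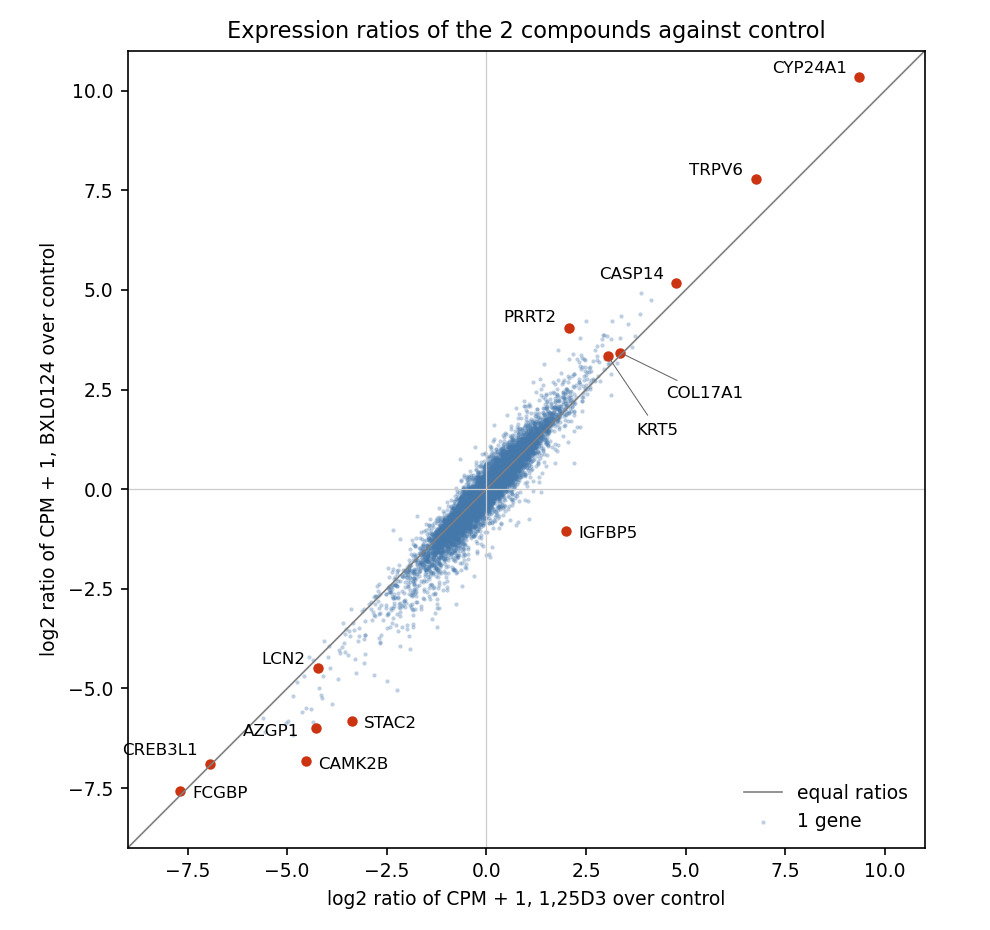
Log2 ratio of CPM + 1 against control with BXL0124 (vertical axis) and with 1,25D3 (horizontal axis), 1 point per gene for the kept genes, with 13 genes named in red and a line where both ratios are equal. CYP24A1 (9.36 and 10.34 on the horizontal and vertical axis) lies at the upper right, FCGBP (−7.69 and −7.58) at the lower left and IGFBP5 (1.99 and −1.06) off the line.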

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

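IGFBP5, which encodes a secreted binding protein of insulin-like growth factors, was singled out after its values were seen. It was the 1 gene called at 2-fold in opposite directions with the compounds. Its log2 ratio to control was 1.99 with 1,25D3 and −1.06 with BXL0124. Its level was 1.52 CPM in control, 8.98 CPM with 1,25D3 and 0.210 CPM with BXL0124. On plain CPM it was 5.91-fold higher with 1,25D3 (4.0 to 9.02) and 7.23-fold lower with BXL0124 (2.86 to 22.5). The difference between the compounds was not tested, because each group had 1 library, and no explanation for it was tested.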

How the results depend on the processing

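TMM scaling, DESeq2 size factors and removal of the length and GC trend were chosen after the data were seen, and the other alternatives were planned. Other thresholds change the counts by construction. At 1.5-fold, 2367 genes were higher and 2668 lower with 1,25D3, 2588 and 3108 with BXL0124, and 245 and 492 with BXL0124 against 1,25D3. At 3-fold the counts were 286 and 321, 410 and 542, and 4 and 26. The share of higher genes between the compounds was 33.2% at 1.5-fold, against 20.9% at 2-fold.

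With a pseudocount of 0.1, 117 genes were higher and 300 lower with BXL0124 against 1,25D3, since a smaller pseudocount shrinks ratios of low values less. Rescaling to TPM gave 180 higher genes in that comparison, and removal of the length and GC trend gave 616 higher genes with 1,25D3 against control. The cause was not tested for either. The other counts of genes and lists stayed within 1.5 times under every alternative run for them.

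The median log2 ratio of ribosomal protein genes with 1,25D3 was 0.023 after removal of the trend and −0.44 before. The corrected interval, −0.04 to 0.07, holds 0, so the lower median was lost and not turned, and its cause is weighed with the length trend. Removing the trend left 94 list medians within their intervals across genes and moved 7, among them those of oxidative phosphorylation. TMM scaling moved 2 list medians and left 100, and a minimum of 5 CPM, no filter and unmatched random lists moved none of 102 beyond the interval or, without an interval, by 1.5-fold. Percentiles crossed their limits more often. Among these crossings, with a minimum of 5 CPM replication-dependent histones lay lower with 1,25D3 (median −0.99, against −0.43), with BXL0124 (−1.24, against −0.40) and between the compounds (percentile 1.18), and TGF-beta and BMP genes lay higher with 1,25D3 (percentile 99.65). After removal of the trend the latter had medians of −0.14 with 1,25D3 and −0.31 with BXL0124, the second at percentile 1.87 against percentile 76.3 before. The Wnt list lay lower with 1,25D3 with no filter (percentile 2.43) and after removal of the trend (percentile 0). The cause was not tested. With no filter, which adds members at or near 0, medians were nearer 0 for innate defence (−0.24 with 1,25D3 and −0.40 with BXL0124), the interferon response (−0.29 and −0.30) and NF-kB genes with 1,25D3 (0.09). After rescaling to TPM, medians with BXL0124 were 0.53 for mitotic, −0.42 for oxidative phosphorylation, −0.36 for ribosomal, −0.12 for p53 target and −0.11 for housekeeping genes. A pseudocount of 0.1 moved 94 ratios of single genes by more than 1.5-fold and left 512 values of genes and lists, and median ratio centring moved 1 list median and left 605 values. No leave-one-out was possible. No paired analysis was possible because each group has 1 library. Depth limits genes near the floor of 3 read pairs, such as ENPP3 with 2 counts in the BXL0124 library.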

Other observations

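Gene families were compared after their values were seen. Mucins, gel-forming and membrane glycoproteins of secretory epithelium, had median log2 ratios of −2.01 with 1,25D3 and −1.93 with BXL0124, below 0 under every scaling tried, with 4 of 6 at least 2-fold lower. MUC1 was higher, at 205 CPM with 1,25D3 and 266 CPM with BXL0124 against 152 CPM. Keratins had a median of 0.52 with 1,25D3 (8 of 23 at least 2-fold higher, 6 lower) and 0.41 with BXL0124 (9 higher, 6 lower), the second of which was 0.85 after removal of the length and GC trend. S100 calcium-binding proteins had medians of −0.97 and −0.85, which after removal of the trend were −0.35 at percentile 1.15 and −0.20 at percentile 13.8. Collagens had medians of 0.75 and 0.36, which were 0.56 and 0.26 after removal of the trend. Laminins had medians of 0.69 and 0.93, which were 0.09 (percentile 70.9) and 0.28 (percentile 92.4) after it. Integrins had medians of 0.32 and 0.28, inside the central 95%, which were −0.18 (percentile 10.9) and −0.15 (percentile 21.3) after it.

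HIF1A, the oxygen-regulated transcription factor, was at 57.2 CPM in control, 507 CPM with 1,25D3 and 794 CPM with BXL0124, whereas the hypoxia list was lower with BXL0124 than with 1,25D3. MALAT1, a long nuclear RNA, was at 1015 CPM in control, 5.08-fold lower with 1,25D3 and 2.03-fold lower with BXL0124. FADS3, a relative of the desaturase FADS1, was at 26.1 CPM in control, 46.6 CPM with 1,25D3 and 98.3 CPM with BXL0124, while FADS2 was at 18.9, 15.2 and 16.8 CPM. Marker genes of other cell types went both ways. PECAM1, an endothelial adhesion molecule, was at 123 CPM in control, 18.5 CPM with 1,25D3 and 13.5 CPM with BXL0124. CSF1R, a macrophage receptor, was at 3.15, 18.0 and 17.3 CPM, and FAP, a fibroblast protease, at 0.341, 4.51 and 7.63 CPM. After removal of the length and GC trend the blood and immune list, with 5 measured members, lay higher with 1,25D3 (percentile 99.7) and with BXL0124 (percentile 99.55).

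The tests of an estrogen-receptor-positive line, of the single control, of scaling, of selection by noise and of length within the ribosomal list were chosen after the results were seen. For the tests of the length and GC trend the bounds were set before, and the demand that an interval clear its bound was added after.

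Ribosomal protein and oxidative phosphorylation genes, with short transcripts, were lower with both compounds, and matrix and mitotic genes were higher. After removal of the trend the ribosomal median nearer 0 was 0.023, so a length or GC trend between libraries is a candidate explanation for that list. Within the ribosomal list Spearman's rho with length was 0.234 with 1,25D3 and 0.115 with BXL0124, too weak to decide. Within the oxidative phosphorylation list it was 0.392 and 0.337, in the direction of the length trend, and no bound was set for that list. The other corrected medians nearer 0 were −0.30 for oxidative phosphorylation, 0.23 for matrix and 0.17 for mitotic genes. Their intervals across genes reach the preset bounds, so the demand added after was not met. Corrected percentiles with 1,25D3 and BXL0124 were 0 and 0.11, 99.95 and 98.89, and 99.61 and 97.69 for these lists in that order. All lay outside the limits for random lists, so the trend as removed here did not take up these shifts in full. Genes of a list are not independent and the interval demand was not met. Whether the trend is the whole cause is therefore not decided for oxidative phosphorylation and mitotic genes. The matrix intervals hold 0 (−0.03 to 0.83 and −0.28 to 0.93), so for that list the trend and the treatment cannot be told apart. For the others the trend stays open as a part or the whole of the cause. The trend itself may come from RNA quality, library preparation, read processing or the cells, which was not tested. Counts came from alignments with duplicates removed, and totals were 38122315 in control, 51421412 with 1,25D3 and 52261152 with BXL0124. Between the treated libraries, with similar totals, Spearman's rho of the log2 ratio with transcript length was 0.044. Whether duplicate removal at unequal depth contributed to the trend was not tested.

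Basal markers were higher and luminal markers lower with both compounds, and the gap between their medians was 1.95 or more on the log2 scale after removal of the trend, which argues against the trend as the whole cause. RNA of an estrogen-receptor-positive luminal line in the control would bring 6 genes together, of which FOXA1 and GATA3 were in excess there, and TFF1 had 24 counts in control and 0 in the treated libraries. Against such a line, PGR and ANKRD30A had no count in any library, and ESR1 was at 0.525 CPM in control beside FOXA1 at 158 CPM, and 8.45-fold higher with 1,25D3 (4.43 to 18.1). The gap was 0.043 between the treated libraries, which compounds acting alike would give with or without a peculiar control, so it cannot decide. Because there is a single control library, a peculiarity of it and an effect of both compounds cannot be told apart. An effect of treatment on the cells stays open and was not tested.

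Ratios were slightly larger with BXL0124 than with 1,25D3. The smallest median of their quotient under median ratio centring, upper quartile, TMM and DESeq2 scaling was 1.06 (1.04 to 1.07 across genes). That argues against a scale factor between libraries. The quotient was not computed after rescaling to TPM. Genes picked by noise in the 1,25D3 library would have smaller ratios with BXL0124, but the smaller median was 1.07 (1.05 to 1.08). A difference in dose, in the compounds or between single libraries stays open and was not tested, so a larger effect of the analog may or may not be the reason.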
